A study of Homo sapiens with 18 samples.

How the data were processed

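Messenger RNA was measured in 18 libraries of the human line GM12878, an EBV-transformed lymphoblastoid B-cell line. The labels place them in 6 groups of 3: a control with a non-targeting guide and stable CRISPR knockouts of the NF-kB subunits p50 (gene NFKB1), p52 (NFKB2), RelB (RELB), cRel (REL) and RelA (RELA). Guides were delivered by lentivirus, cells were selected with puromycin at 3 µg/ml for 5 days, and knockouts were checked by immunoblot, per the labels' protocols. RNA was isolated on columns with DNase treatment, polyadenylated RNA was taken from 1 µg of total RNA, and libraries were made with a directional kit, per the labels' protocols. The labels call the replicates biological; whether they were separate cultures from the start of selection is not given in the sources used here.

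Reads were aligned to GRCh37 with STAR 2.5.2b, counted with featureCounts 1.5.1 and normalised with DESeq2 1.14.1, per the submitters' processing notes. The annotation release, any filter on genes and whether counting used the strand are not given in the sources used here, so a gene and an overlapping or antisense partner were not separated. The deposited unit was a normalised signal, and each library's values were read counts divided by a single size factor. This was checked: with 1 size factor per library, 100% of 308790 values came back as whole reads within 0.0001, with a largest distance of 7.05e-05. Size factors computed here from those reads by the median-ratio method equalled the deposited ones, so a planned rescaling by median ratios moved nothing and is not counted as a check. One table of 17155 genes was used, with gene symbols and Ensembl identifiers as it gives them. A GENCODE 29 annotation on GRCh38 served only for transcript length and GC content by gene identifier, found for 99.85% of tested genes; no coordinates are printed.

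Recovered reads per library ranged from 15.2 to 37.5 M reads with a median of 22.1 M reads, and 1 read was worth 0.646 to 1.46 units of the normalised read count. Between 15419 and 16205 genes per library had at least 1 read. Replicates varied by more than counting error: over the 18 pairs of libraries within groups, the mean chi-square per gene was 3.31 to 34.2. P-values measure only the spread between these libraries.

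The groups, comparisons, tests, gene lists, other settings and the rule for naming genes were fixed before the data were examined. The main test was limma 3.58.1 with an intensity trend on log2(value + 1), in one fit of all 18 libraries with a mean for each group, two-sided, for the 12381 genes with a mean of at least 10. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Each knockout was compared with the control, a moderated F-test compared the 5 knockouts with one another, and each of the 10 pairs of knockouts was tested directly. Fold changes come from this log2 scale, which understates changes of genes with few reads. The replicate numbers were not treated as pairs, because in 0 of 5 knockouts did all 3 libraries correlate above 0.1 with the control of the same number. Across all groups, however, 16 of 18 libraries correlated best with a library of their own number. This points to a shared effect of the replicate number, which the main fit did not use. Between knockouts, all 3 such correlations were above 0.1 for the cRel-labelled and p50 libraries (0.200, 0.189 and 0.165), and the direct test of that pair and the F-test did not use this; with a replicate block the pair differed in 4215 genes against 3855, with 3846 called in both.

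The rule named (a) the 5 subunit genes; (b) per knockout, the 6 highest and 6 lowest log2 fold changes among called genes with a symbol, where all 3 knockout libraries lay on one side of all 3 controls and the higher group's mean was at least 100; and (c) up to 3 called members with the smallest p from the NF-kB feedback list, the NF-kB target list and up to 4 other called lists with the smallest p. From the F-test it named the 6 genes with the smallest p and a mean of at least 100. A few genes that the rule named are not reported here. Of the 668 entries in 28 gene lists, 628 matched a gene in the table. The lists held NF-kB subunits, NF-kB feedback and signalling, NF-kB targets in EBV-transformed B cells, BCL2 family and apoptosis regulators, chemokines and cytokines, B-cell activation surface molecules, B-cell identity and receptor signalling, the plasma-cell programme, germinal-centre B-cell genes, EBV super-enhancer and growth genes, MYC and ribosome biogenesis targets, proliferation, p53 targets, interferon-stimulated genes, MHC class I and class II presentation, cholesterol synthesis, the ATF4 and unfolded-protein response, glycolysis and hypoxia, oxidative phosphorylation, migration and cytoskeleton, mitochondrially encoded transcripts, cytosolic ribosomal proteins, immediate-early and stress genes, replication-dependent histones, and markers of T and NK cells, of monocytes and macrophages, and of epithelial cells and fibroblasts. The 26 lists with at least 5 tested members were compared with the other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists. The test was repeated with an estimated correlation, which for the pairs of knockouts was chosen after seeing the data. Some genes stand in more than 1 list.

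The settings fixed in advance were pseudocounts of 0.5 and 10, no filter, a mean of at least 100, quantile normalization, only the 2 groups compared, library weights, robust variance moderation, a replicate block, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Chosen after seeing the data were TMM rescaling, a correction of each library for transcript length and GC content, control 3 and p52 3 left out together, and reads thinned to one depth. The test was also run on simulated data for all 18 libraries. Counts were drawn from each gene's mean over all libraries, each library's depth and each gene's spread, and the changes were placed in the cRel-labelled group. Of 50 genes changed at each size among 12381, limma recovered 20 at 1.25-fold, 42 at 1.5-fold, 47 at 2-fold and 50 at 4-fold, and called 8 unchanged genes. One simulation of 100 draws set 2 unchanged groups against 1 shared simulated control in each draw. All groups were drawn from the deviations of the 18 libraries from their group means, with random sign. It gave the covariance that a shared control of such pooled spread produces, not that of the 3 real controls. Replicate numbers were ignored, and the same simulation served for all pairs of knockouts. R 4.3.3, python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.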

Results

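The libraries measured polyadenylated RNA of GM12878 cells, an EBV-transformed B-cell line in which the viral protein LMP1 keeps NF-kB active, after stable CRISPR knockout of each of the 5 NF-kB subunits. There were 3 libraries for each of the 5 knockouts and 3 for the control with a non-targeting guide. The comparisons asked which genes depend on each subunit and how the subunits differ. Values are deposited normalised read counts, given as mean ± SD with n = 3 in each group unless stated. Fold changes and adjusted p come from limma on log2(value + 1). List members given by a log2 fold change alone are examples that passed the test and were chosen after their values were seen.

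Recovered reads were 20.9, 23.5 and 37.5 M in the control libraries 1, 2 and 3. They were 22.1, 24.6 and 26.8 M in the cRel-labelled libraries, 24.4, 20.3 and 26.6 M in the p50 knockout, and 18.4, 18.7 and 30.5 M in the p52 knockout. The other groups had 20.4, 20.7 and 19.8 M in the RelA knockout and 15.2, 23.1 and 22.0 M in the RelB-labelled libraries. The 10 most abundant genes took 5.52% to 7.48% of reads per library. Mitochondrially encoded transcripts took 4.31% ± 0.677 of reads in the control, 2.90% ± 0.919 in the p50 knockout and 5.11% ± 0.299 in the RelB-labelled libraries. Ribosomal protein genes took 6.71% ± 0.670 in the control, from 5.97% ± 0.241 in the RelA knockout to 9.16% ± 0.474 in the RelB-labelled libraries. The first principal component held 51.1% of the variance and separated the RelB-labelled libraries, at 49.8 to 52.7, from the controls, at -26.6 to -20.8. Control 3 stood apart from the other controls in transcript length: the rank correlation of its deviation from the control mean with length was -0.65 across genes, against 0.38 and 0.57 in controls 1 and 2. Within their own groups p52 library 3 (-0.54) and RelA library 2 (-0.45) stood apart in the same direction, and the deviations of p52 library 3 correlated with those of control 3 at 0.397. These correlations are across genes, which are not independent replicates.

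The targeted genes were examined first, as a check of the labels. In the p50 knockout NFKB1 (ENSG00000109320) fell 1.51-fold, from 7066 ± 305 in the control to 4685 ± 56.4 (log2 fold change -0.59, SE 0.06, adjusted p = 3.1e-07 by limma). In the p52 knockout NFKB2 (ENSG00000077150) fell from 8566 ± 138 to 6320 ± 172 (-0.44, SE 0.06, adjusted p = 1.5e-06). In the RelA knockout RELA (ENSG00000173039) fell from 2208 ± 31.6 to 1368 ± 35.4 (-0.69, SE 0.06, adjusted p = 2.6e-07). In each of these all 3 knockout libraries lay below all 3 controls. Against the label, RELB (ENSG00000104856) rose in the RelB-labelled libraries, from 3319 ± 158 to 4107 ± 170 (0.31, SE 0.06, adjusted p = 1.7e-04). REL (ENSG00000162924) stood at 1554, 1717 and 856 in the control libraries and at 1298, 1315 and 1282 in the cRel-labelled libraries (-0.02, SE 0.19, adjusted p = 0.96). Without control 3 the difference in REL was -0.33 (adjusted p = 0.31), and without control 2 it was 0.17. Insertions or deletions made by CRISPR need not lower the amount of mRNA, so these values do not decide the labels of these 6 libraries. They are written as cRel-labelled and RelB-labelled throughout. The fall of RELA favours the RelA label, since the RELA means in the other knockouts were 2183 to 2689. The labels' protocols also state a check by immunoblot. The mRNA values alone do not settle the RelA label, because RELB was also lowest in the RelA knockout. An exchange of these 2 labels is not excluded by them. Every result given for the cRel, RelA and RelB groups therefore rests on the labels. The fall of NFKB2 does not single out the p52 knockout either. NFKB2 stood at 6671 ± 226 in the RelA knockout, where library 3, at 6411, lay below p52 library 1, at 6508. NFKB1 was also low in the RelA knockout, at 5138 ± 288.

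The subunit genes also changed in libraries with another target. In the RelA knockout RELB fell 1.76-fold to 1887 ± 127 (adjusted p = 1.3e-08 by limma), NFKB1 fell to 5138 ± 288 (adjusted p = 3.4e-05) and NFKB2 fell to 6671 ± 226 (adjusted p = 2.8e-04). RELB rose to 4322 ± 243 in the cRel-labelled libraries, 3894 ± 196 in the p50 knockout and 4260 ± 49.4 in the p52 knockout. In the RelB-labelled libraries NFKB2 rose to 10862 ± 430 (adjusted p = 1.6e-05) and NFKB1 fell to 5794 ± 64.6 (adjusted p = 2.8e-04, with a range over settings of 1.4e-05 to 0.0501, the last after quantile normalization). RELA rose to 2689 ± 289 in the p52 knockout (0.28, adjusted p = 1.0e-03). In the RelB-labelled libraries RELA stood at 2461 ± 33.8 (0.16, adjusted p = 0.037) and REL at 938 ± 65.1 (-0.49, adjusted p = 0.024). Both calls depended on single libraries. For RELA the adjusted p was 0.054 without control 1, 0.089 without control 2, 0.058 without control 3, and 0.056, 0.091 and 0.070 without RelB-labelled libraries 1, 2 and 3. For REL it was 0.12 without control 1, 0.17 without control 2, and 0.056 and 0.072 without RelB-labelled libraries 1 and 3.

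**Figure D1:**
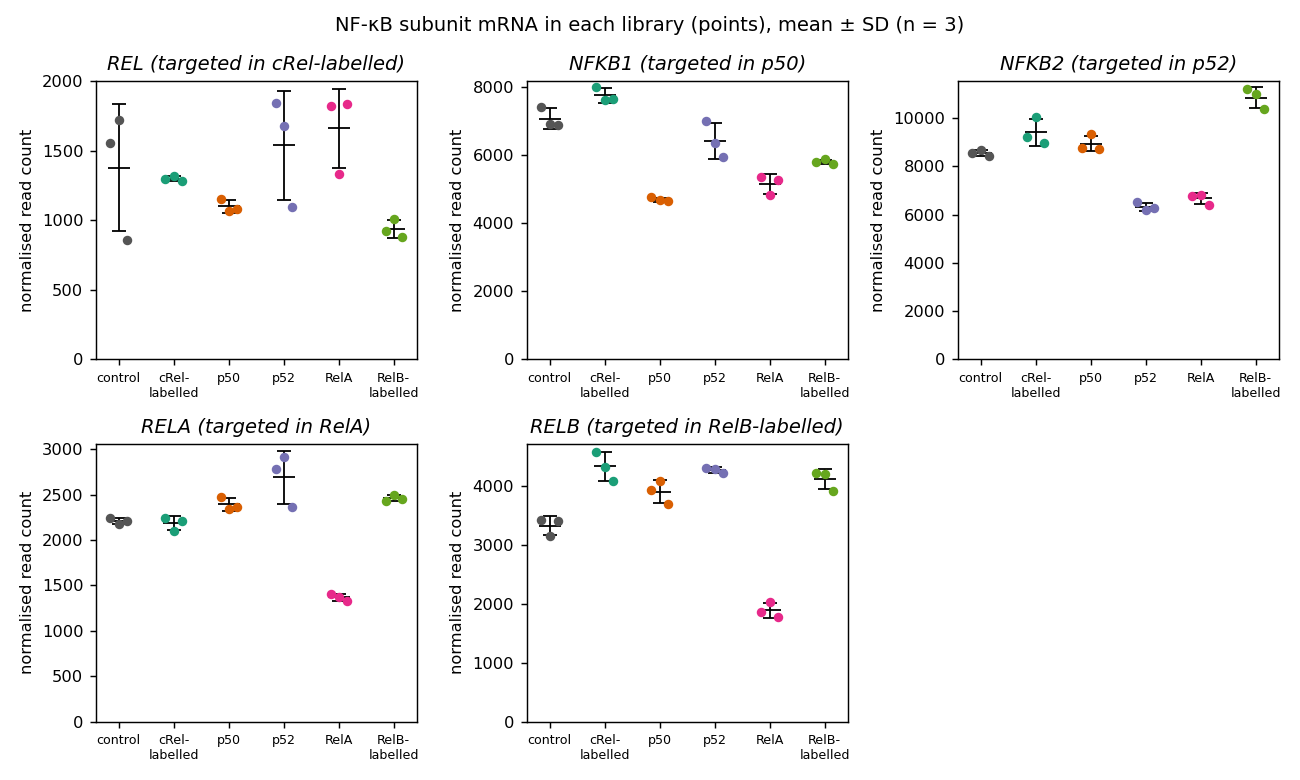
Normalised read counts of the 5 NF-kB subunit genes, 1 panel per gene, in the control and the 5 knockout groups; each point is a library, and the long line and error bar are the mean and SD of 3. The means of NFKB1, NFKB2 and RELA were lowest in the group with that target, though single NFKB2 values of the p52 and RelA knockouts overlapped. RELB in the RelB-labelled libraries lay at 4107 against 3319 in the control.

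In the cRel-labelled libraries the gene with the lowest fold change was CCL22, a chemokine that attracts T cells, which fell 5.19-fold from 2559 ± 245 to 494 ± 64.0 (log2 fold change -2.37, SE 0.08, adjusted p = 9.8e-16 by limma). The epithelial barrier genes SPRR2A and SPRR2D, close paralogs whose reads can be split between them, fell 3.70-fold and 3.31-fold. The kinesin KIF26B fell from 1184 ± 105 to 459 ± 12.8. FSTL3, a secreted follistatin-like protein, fell 2.55-fold, and CD93, a lectin-like receptor, fell from 249 ± 35.6 to 97.4 ± 7.59. Highest was TNS3, a focal adhesion protein, which rose 3.35-fold from 59.4 ± 7.38 to 200.3 ± 9.32. IPCEF1 rose 2.56-fold from 210.4 ± 42.2 to 534 ± 30.5, and SEMA5A, KIAA1671, FRAS1 and TGM2 rose 2.53-fold to 2.87-fold. Of the genes tested, 516 rose and 238 fell, 93 of these 754 by at least 2-fold; edgeR called 814 and DESeq2 928.

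Of 39 measured NF-kB targets in EBV-transformed B cells, 4 rose and 9 fell in the cRel-labelled libraries (8 and 17 adjusted over the list alone). The list stood lower than other genes by camera (median -0.15, adjusted p = 0.0066, and adjusted p = 0.33 with an estimated correlation). CCL22 led the fall, with DUSP2, a nuclear phosphatase, down from 3466 ± 314 to 1864 ± 115 and EBI3, a cytokine subunit, down from 4598 ± 313 to 3478 ± 83.1. The feedback and signalling list was not called (adjusted p = 0.10), yet 3 of its 26 members rose and 0 fell (7 and 4 adjusted over the list alone). CYLD, a deubiquitinase that restrains NF-kB, rose from 4421 ± 291 to 6255 ± 135 (adjusted p = 1.7e-05). NFKBIZ rose from 451 ± 49.7 to 665 ± 27.2, and TRAF3, which restrains the non-canonical pathway, from 5543 ± 411 to 6910 ± 346. B-cell identity genes stood higher (5 of 27 rose, 1 fell, and 7 and 1 adjusted over the list alone; camera adjusted p = 0.0041, and adjusted p = 0.25 with an estimated correlation). Among them CD22, an inhibitory receptor, rose from 3943 ± 160 to 5183 ± 189, and the B-cell factors EBF1 and POU2AF1 rose 1.33-fold and 1.29-fold.

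Further lists in the cRel-labelled libraries were called with few single genes past the test. Germinal-centre genes stood higher (3 of 18 rose, 2 fell; adjusted p = 0.030, and adjusted p = 0.33 with an estimated correlation), with BCL6, the germinal-centre repressor, up by 0.90. MHC class II genes stood higher with 1 of 16 risen and 0 fallen (adjusted p = 0.012, and adjusted p = 0.48 with an estimated correlation). So did the 5 subunit genes, a list that holds the targeted REL, with 1 risen and 0 fallen (adjusted p = 0.040, and adjusted p = 0.33 with an estimated correlation). MYC and ribosome biogenesis targets stood lower (0 of 24 rose, 2 fell; adjusted p = 0.0066, and adjusted p = 0.33 with an estimated correlation). In that list NOP16 fell to 1418 ± 22.3 (adjusted p = 0.0080, and 0.068 without control 3). LDHA fell to 37963 ± 366 (adjusted p = 0.014) but missed the threshold without control 1 (0.066), control 3 (0.086), or cRel-labelled libraries 1 (0.057) or 2 (0.055). The list of the ATF4 and unfolded-protein response stood lower by camera (adjusted p = 0.010, and adjusted p = 0.33 with an estimated correlation). Of its 25 genes 1 rose and 4 fell, with PHGDH and ASNS, enzymes of serine and asparagine synthesis, at -0.43 and -0.27. Proliferation genes stood lower with 0 of 27 past the test singly by limma or edgeR, 1 by DESeq2 and 6 at an unadjusted p under 0.05 (median -0.09, adjusted p = 0.0078, and adjusted p = 0.56 with an estimated correlation). Glycolysis genes (0 of 26 rose, 3 fell; adjusted p = 0.018) and oxidative phosphorylation genes (0 of 25 past the test by limma or edgeR, 1 by DESeq2 and 5 unadjusted; adjusted p = 0.0018) stood lower, with adjusted p = 0.47 and adjusted p = 0.57 with an estimated correlation. Cytosolic ribosomal proteins had a median of -0.18 with 0 of 33 past the test by limma, edgeR or DESeq2 and 14 lower at an unadjusted p under 0.05 (adjusted p = 5.1e-07, and adjusted p = 0.47 with an estimated correlation). Without control 3, the library rich in short transcripts, the median was -0.09.

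Several of these list calls depended on single libraries. Without control 2 the adjusted p was 0.064 for the subunit genes, 0.053 for germinal-centre genes and 0.20 for MHC class II, and without control 3 it was 0.13, 0.075 and, for oxidative phosphorylation, 0.18. Leaving out cRel-labelled library 1 gave 0.074 for the subunits and 0.056 for germinal-centre and glycolysis genes. Leaving out library 2 gave 0.054 for the subunits, and leaving out control 1 gave 0.35 for glycolysis. Over all settings the adjusted p ran from 0.010 to 0.31 for germinal-centre genes, from 0.0010 to 0.35 for glycolysis, from 9.3e-04 to 0.052 for MYC targets and from 0.0032 to 0.053 for the ATF4 and unfolded-protein response. The highest values came without genes of mean under 100, without control 1, after quantile normalization and after the length correction. The count of called genes was 481 without control 3, 475 without cRel-labelled library 2 and 448 without library 3.

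In the p50 knockout, DBNDD1 rose 5.01-fold from 55.2 ± 8.74 to 279 ± 5.66 (log2 fold change 2.33, SE 0.17, adjusted p = 1.9e-09 by limma) and ENPP2, which makes lysophosphatidic acid, rose 4.47-fold from 189 ± 20.6 to 848 ± 60.6. PADI2, a protein deiminase, rose 4.15-fold, the endocytic receptor LRP1 3.39-fold, the chemokine scavenger ACKR3 3.16-fold and MAP7D2 3.11-fold. FSTL3 fell 4.18-fold. The transcription factor GATA3 fell 4.17-fold from 444 ± 46.5 to 106 ± 16.3, and the chemokine receptor CXCR3 fell 4.12-fold from 613 ± 73.2 to 150 ± 35.5. BCAR3 and the prostaglandin receptor PTGER4 fell 3.85-fold and 2.83-fold. In all, 2109 genes rose and 2430 fell, 282 of these 4539 by at least 2-fold; edgeR called 4588 and DESeq2 4589.

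Cell-cycle genes fell together in the p50 knockout: 26 of 27 proliferation genes fell and 0 rose (26 and 0 adjusted over the list alone; median -0.41, camera adjusted p = 5.7e-15, and adjusted p = 0.17 with an estimated correlation). RRM2, which supplies deoxynucleotides, fell from 8690 ± 426 to 5090 ± 383, the replication licensing factor CDC6 from 2516 ± 127 to 1683 ± 99.2, and the mitotic kinase BUB1 from 3956 ± 96.3 to 2739 ± 223. MYC and ribosome biogenesis targets fell in 14 of 24 and rose in 0 (adjusted p = 2.9e-04, and adjusted p = 0.17 with an estimated correlation), with the nucleolar proteins NOP56, NOP58 and NOP2 at -0.41, -0.37 and -0.34. Targets of p53 rose in 13 of 26 and fell in 1 (adjusted p = 2.0e-04, and adjusted p = 0.17 with an estimated correlation). The pro-apoptotic BBC3 rose 1.62-fold, the repair factor XPC 1.42-fold, and TP53INP1 2.02-fold from 657 ± 134 to 1343 ± 334.

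NF-kB feedback genes went both ways in the p50 knockout (3 of 26 rose, 6 fell; camera adjusted p = 0.93), as did the NF-kB targets (10 of 39 rose, 14 fell; adjusted p = 0.54). NFKBIA, the inhibitor IkB-alpha, fell 1.74-fold from 6952 ± 316 to 3988 ± 211 (adjusted p = 1.7e-08 by limma), NFKBIZ fell 1.39-fold and TRAF1 fell 1.22-fold. CCL22 fell to 1355 ± 55.2 and the AP-1 member JUNB to 3030 ± 190.

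Of 23 plasma-cell genes 3 rose and 13 fell (4 and 13 adjusted over the list alone; adjusted p = 0.0034, and adjusted p = 0.17 with an estimated correlation). PRDM1, the regulator of plasma-cell fate, fell by 1.04 on the log2 scale, the chaperone HSP90B1 by 0.53, and the surface proteoglycan SDC1 rose by 0.87. Of 18 germinal-centre genes 8 fell and 1, GCSAM at 0.70, rose (adjusted p = 0.013, and adjusted p = 0.17 with an estimated correlation). Of 17 migration and cytoskeleton genes 7 fell and 3 rose (adjusted p = 0.022, and adjusted p = 0.18 with an estimated correlation). They included the intermediate filament VIM at -1.13 and the chemokine receptor CXCR4 at -0.85. Interferon-stimulated genes fell in 16 of 29 and rose in 5 (adjusted p = 0.016, and adjusted p = 0.53 with an estimated correlation), with IFI44L at -1.88 and IFIT1 at -1.82 but IFIT3 at 0.64. MHC class I genes fell in 7 of 20 and rose in 1 (adjusted p = 0.037, and adjusted p = 0.51 with an estimated correlation), with the immunoproteasome subunit PSMB8 at -0.54. Without p50 library 1 the adjusted p was 0.086 for interferon-stimulated genes and 0.086 for MHC class I, and it was 0.13 for MHC class I without control 3. Over all settings the highest adjusted p was 0.44 for interferon-stimulated genes (mean of at least 100) and, after quantile normalization, 0.48 for MHC class I, 0.17 for migration and 0.059 for MYC targets.

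Metabolic and stress lists also moved in the p50 knockout. Of 13 mitochondrially encoded transcripts 12 fell and 0 rose (0 and 13 adjusted over the list alone; median -0.85, adjusted p = 2.0e-04, and adjusted p = 0.51 with an estimated correlation). The cytochrome oxidase transcripts MT-CO2 and MT-CO3 and the complex I transcript MT-ND1 fell 1.64-fold, 1.84-fold and 1.85-fold. The mitochondrial share of reads was 3.55%, 1.85% and 3.30% in p50 libraries 1, 2 and 3. Cholesterol synthesis genes fell in 12 of 21 and rose in 2 (adjusted p = 0.0029, and adjusted p = 0.47 with an estimated correlation), with INSIG1 at -0.53 and SQLE at -0.42. Immediate-early and stress genes fell in 8 of 20 and rose in 2 (adjusted p = 0.0087, and adjusted p = 0.17 with an estimated correlation), with the transcription factors EGR2 and KLF2 at -1.07 and -1.10. Oxidative phosphorylation genes fell in 9 of 25 and rose in 0 (adjusted p = 0.021, and adjusted p = 0.79 with an estimated correlation; 0.39 without control 3). Glycolysis genes rose in 10 of 26 and fell in 3 (adjusted p = 0.034, and adjusted p = 0.53 with an estimated correlation; 0.17 without control 2).

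In the p52 knockout the cell adhesion molecule L1CAM rose 15.5-fold, from 7.28 ± 1.46 to 130 ± 34.2 (log2 fold change 3.96, SE 0.35, adjusted p = 9.9e-09 by limma). The transporter ABCC3 rose 10.1-fold from 10.5 ± 3.84 to 111 ± 9.75, and the proton pump ATP4A 9.60-fold from 31.4 ± 11.2 to 301 ± 49.9. TMPRSS6, PLCH2 and MAP7D2 rose 6.52-fold, 6.05-fold and 5.26-fold. C3orf20 fell 2.92-fold, BCAR3 2.91-fold, and CXCR3 2.71-fold. The fructose transporter SLC2A5 fell 2.69-fold from 1368 ± 81.6 to 509 ± 40.8, FAM129C 2.55-fold and DACT1 2.44-fold. In all, 3028 genes rose and 3267 fell, 605 of these 6295 by at least 2-fold, and of those 605 genes 522 rose. edgeR called 6381 genes and DESeq2 6268.

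Of the 39 NF-kB targets, 19 rose and 10 fell in the p52 knockout (20 and 10 adjusted over the list alone; median 0.20, camera adjusted p = 0.036, and adjusted p = 0.50 with an estimated correlation; 0.058 without control 2 and 0.084 with only the p52 and control libraries). The lymphocyte receptor SLAMF1 rose from 2852 ± 219 to 5602 ± 366, PLEK rose 1.69-fold and the homing receptor CCR7 1.67-fold. The feedback list was not called (12 of 26 rose, 4 fell; adjusted p = 0.17), with NFKBIE, another IkB protein, up to 3204 ± 224 from 2233 ± 136, NFKBIA down to 5110 ± 104 and the kinase CHUK down to 1204 ± 39.1. B-cell activation molecules rose in 15 of 28 and fell in 4 (adjusted p = 0.0024, and adjusted p = 0.16 with an estimated correlation), including CD274, the ligand PD-L1, at 0.88, and the receptors TNFRSF13C at 0.98 and CD40 at 0.66.

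All 27 proliferation genes fell in the p52 knockout (median -0.63, adjusted p = 2.9e-15 by camera, and adjusted p = 0.16 with an estimated correlation), with RRM2 down 1.93-fold, CDC6 1.92-fold and the mitotic kinase AURKA 1.65-fold. MYC and ribosome biogenesis targets fell in 19 of 24 and rose in 0 (0 and 20 adjusted over the list alone; adjusted p = 7.1e-09, and adjusted p = 0.11 with an estimated correlation), with NOP56, NOP2 and nucleolin (NCL) down 1.61-fold, 1.57-fold and 1.51-fold. Targets of p53 rose in 14 of 26 and fell in 2 (adjusted p = 0.0014, and adjusted p = 0.22 with an estimated correlation), with TP53INP1 up 3.65-fold from 657 ± 134 to 2383 ± 318, BBC3 1.84-fold and ZMAT3 1.64-fold. Glycolysis and hypoxia genes rose in 14 of 26 and fell in 3 (adjusted p = 0.0016, and adjusted p = 0.45 with an estimated correlation), with the glycolytic enzymes ENO2, ALDOC and PFKFB4 up 1.94-fold, 2.44-fold and 2.49-fold. Plasma-cell genes fell in 13 of 23 and rose in 4 (adjusted p = 0.036, and adjusted p = 0.22 with an estimated correlation), with PRDM1 at -1.26 and HSP90B1 at -0.77, and over all settings the adjusted p ran from 0.0053 to 0.096, the last after quantile normalization. Oxidative phosphorylation genes fell in 9 of 25 and rose in 0 (adjusted p = 0.041, and adjusted p = 0.84 with an estimated correlation), but the adjusted p was 0.33 without control 3 and 0.21 and 0.13 without p52 libraries 1 and 2.

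In the RelA knockout FSTL3 fell 5.36-fold, from 763 ± 62.1 to 141 ± 11.2 (log2 fold change -2.42, SE 0.11, adjusted p = 4.9e-12 by limma). The TNF receptor family members TNFRSF18 (GITR) and TNFRSF9 (4-1BB) fell 4.45-fold, from 637 ± 48.3 to 145 ± 35.4, and 3.58-fold, from 171 ± 30.3 to 47.1 ± 9.22. KREMEN2 fell 2.94-fold, the macrophage growth factor CSF1 fell 2.47-fold from 1134 ± 83.6 to 457 ± 10.9, and UBE2QL1 fell 2.24-fold. MEGF6 rose 3.37-fold from 51.2 ± 9.15 to 173 ± 9.98. CRYM, the collagen COL5A3 and FAM129C rose 2.77-fold, 2.70-fold and 2.58-fold, and LGALS3BP and the antiviral gene OASL rose 2.55-fold and 2.37-fold. There were 361 genes that rose and 326 that fell, 72 of these 687 by at least 2-fold; edgeR called 671 and DESeq2 795.

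NF-kB genes fell as a group in the RelA knockout. Of 39 targets 21 fell and 3 rose (4 and 24 adjusted over the list alone; median -0.31, camera adjusted p = 1.3e-15), and this call held with an estimated correlation (adjusted p = 0.0063). CD83, a marker of activated B cells, fell from 4937 ± 323 to 2812 ± 88.9. In the feedback list 6 of 26 fell and 1 rose (1 and 9 adjusted over the list alone; adjusted p = 1.5e-05, and adjusted p = 0.059 with an estimated correlation). NFKBIA fell 2.12-fold from 6952 ± 316 to 3287 ± 334, NFKBIE 1.64-fold, and BIRC3, an inhibitor of apoptosis, 1.44-fold. Of the 5 subunit genes 4 fell and 0 rose (adjusted p = 4.3e-08, and adjusted p = 0.011 with an estimated correlation), but this list holds the targeted RELA, and without it too few genes were left for camera. B-cell activation molecules fell in 7 of 28 and rose in 4 (adjusted p = 0.012, and adjusted p = 0.14 with an estimated correlation), with the adhesion molecule ICAM1 at -0.60 and CD69 at -0.81. Among 21 chemokines and cytokines 7 fell and 3 rose (adjusted p = 0.031, and adjusted p = 0.50 with an estimated correlation), with IL32 at -1.08, EBI3 at -0.64 and the interferon-induced CXCL9 at 1.92. Without control 3 that list's median was 0.05 (adjusted p = 0.26), and without RelA library 1 the adjusted p was 0.094. Over all settings it ran from 0.0016 to 0.26, with 0.23 after the length and GC correction.

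Interferon-stimulated genes rose in 13 of 29 and fell in 0 in the RelA knockout (20 and 0 adjusted over the list alone; median 0.31, adjusted p = 1.0e-15 by camera), and the call held with an estimated correlation (adjusted p = 0.025). IFIT3 rose from 1499 ± 167 to 2297 ± 106, USP18 from 312 ± 15.5 to 471 ± 33.4, and MX1 by 0.44 on the log2 scale. Histone genes, whose polyadenylated forms and shared sequences make counts uncertain, rose in 6 of 12 and fell in 0 (adjusted p = 3.6e-06, and adjusted p = 0.12 with an estimated correlation). Migration genes rose in 3 of 17 and fell in 0 (adjusted p = 0.0018, and adjusted p = 0.075 with an estimated correlation), with the integrin ITGB1 at 0.39 and VIM at 0.28. Cholesterol synthesis genes stood lower, with 4 of 21 fallen (0 and 11 adjusted over the list alone; adjusted p = 2.4e-07, and adjusted p = 0.12 with an estimated correlation). Of these, FDPS fell to 3688 ± 136 (adjusted p = 0.0091, and 0.057 without control 3). MVD stood at 3498 ± 306 (adjusted p = 0.024, and 0.081, 0.11 and 0.17 without control 1, control 3 and RelA library 3). MVK stood at 1054 ± 31.7 (adjusted p = 0.026). MVK missed the threshold without control 1 (0.056), control 3 (0.18) or RelA libraries 1 (0.057), 2 (0.061) or 3 (0.11).

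Energy and translation lists stood lower in the RelA knockout with few single genes past the test. Glycolysis genes fell in 5 of 26 and rose in 0 (1 and 12 adjusted over the list alone; adjusted p = 1.3e-06, and adjusted p = 0.12 with an estimated correlation), with PFKFB4 at -0.65. Oxidative phosphorylation genes had a median of -0.17 with 0 of 25 past the test by limma, edgeR or DESeq2 and 7 lower at an unadjusted p under 0.05 (adjusted p = 6.5e-05, and adjusted p = 0.55 with an estimated correlation; 0.15 without control 3). Ribosomal proteins had a median of -0.19 with 0 of 33 past the test by the same tools and 13 lower at an unadjusted p under 0.05 (adjusted p = 6.9e-08, and adjusted p = 0.50 with an estimated correlation), and a median of -0.10 without control 3. MHC class II genes stood lower (1 of 16 rose, 1 fell; adjusted p = 0.030, and adjusted p = 0.55 with an estimated correlation), but the adjusted p was 0.45 without control 3 and 0.058 and 0.083 without RelA libraries 1 and 3. The number of called genes was 442 without control 1, 454 without RelA library 1 and 413 without RelA library 3.

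The RelB-labelled libraries differed most from the control in number of genes. TBC1D30 rose 37.5-fold, from 18.9 ± 4.24 to 735 ± 26.4 (log2 fold change 5.23, SE 0.26, adjusted p = 2.6e-13 by limma). The heat-shock genes HSPA6, from 3.12 ± 1.78 to 124 ± 43.0, and HSPA1B, from 146 ± 8.90 to 2042 ± 776, rose 31.1-fold and 13.3-fold, with a wide spread and with reads that close paralogs can share. The immediate-early and stress list, which holds HSPA1B, went both ways in these libraries (11 of 20 rose, 7 fell; median 0.42, camera adjusted p = 0.11), with a summed value of 35132 ± 1938 against 26081 ± 1915 in the control. It was not called in the cRel, p52 and RelA groups (adjusted p = 0.13, 0.22 and 0.81). TSPAN11 rose 20.7-fold, the interferon-inducible GTPase GBP6 19.7-fold and the actin-binding CALD1 15.2-fold. PTGER4 fell 10.1-fold from 262 ± 49.1 to 26.2 ± 11.6, CXCR3 8.53-fold and BCAR3 8.51-fold. The transcription factor HHEX fell 6.20-fold, BCL6 6.14-fold from 237 ± 38.3 to 37.6 ± 4.33, and the histone HIST1H2BC 5.30-fold. In all, 4098 genes rose and 4293 fell, 1501 of these 8391 by at least 2-fold; edgeR called 8414 and DESeq2 8256.

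All 27 proliferation genes fell in the RelB-labelled libraries (median -0.95, camera adjusted p = 7.9e-14, and adjusted p = 0.21 with an estimated correlation), with CDC6 down 2.74-fold, the mitotic cyclin CCNB1 2.59-fold and RRM2 2.44-fold. MYC and ribosome biogenesis targets fell in 22 of 24 and rose in 0 (adjusted p = 2.2e-07, and adjusted p = 0.20 with an estimated correlation), with RRS1, MRTO4 and NOP56 down 2.46-fold, 2.22-fold and 2.16-fold. Ribosomal proteins went the other way, with 27 of 33 risen and 0 fallen (29 and 0 adjusted over the list alone; median 0.39, adjusted p = 1.6e-04, and adjusted p = 0.52 with an estimated correlation). RPS27 rose 1.66-fold and RPL14 1.35-fold. Histone genes fell in 10 of 12 and rose in 0 (median -1.57, adjusted p = 2.5e-04, and adjusted p = 0.40 with an estimated correlation), with the linker histone HIST1H1C down 5.23-fold, HIST1H2BK 4.16-fold and HIST1H2AC 3.39-fold.

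Of the 39 NF-kB targets, 23 rose and 9 fell in the RelB-labelled libraries (23 and 9 adjusted over the list alone; median 0.34, adjusted p = 0.0085 by camera, and adjusted p = 0.40 with an estimated correlation). The list holds the targeted RELB, which is among those that rose. SLAMF1 rose 3.41-fold to 9704 ± 289, while the cytokine TNF fell 5.03-fold from 380.0 ± 45 to 74.6 ± 5.25 and the stress gene IER3 fell 4.11-fold. The feedback list was not called (11 of 26 rose, 6 fell; adjusted p = 0.19), with NFKBIE up to 4318 ± 89.4, BIRC3 up to 11647 ± 49.0 and NFKBIA down to 4084 ± 164. B-cell activation molecules rose in 17 of 28 and fell in 7 (adjusted p = 0.0051, and adjusted p = 0.21 with an estimated correlation), with CD274 at 1.89, CD80, a costimulatory ligand, at 1.34, and CD83 at -0.54. Interferon-stimulated genes rose in 16 of 29 and fell in 5 (adjusted p = 0.035, and adjusted p = 0.52 with an estimated correlation), with MX1 at 0.65 but IFIT1 at -1.64.

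**Figure D2:**
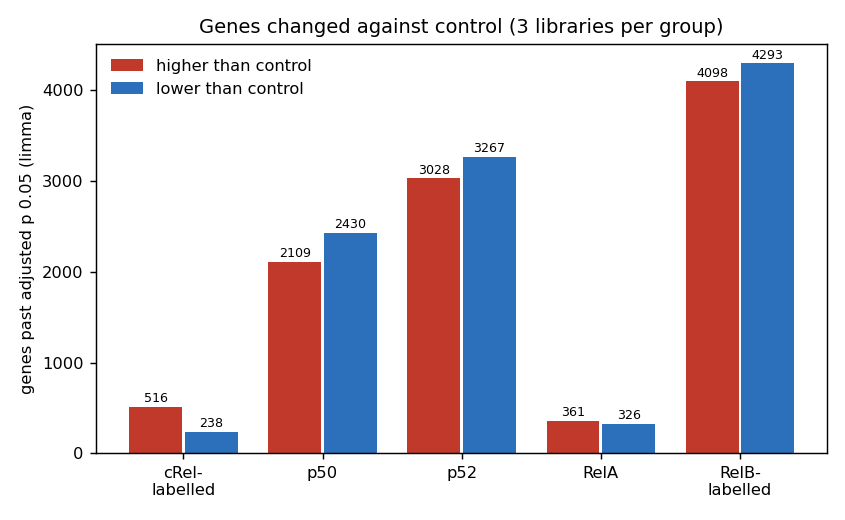
Bars give the number of genes called higher (red) and lower (blue) than the control by limma (adjusted p under 0.05) in each knockout, 3 libraries per group. The sum of both bars ran from 687 in the RelA knockout to 8391 in the RelB-labelled libraries.

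The remaining lists were not called in any knockout by camera. Of 25 BCL2 family genes, 2 rose and 3 fell in the cRel-labelled libraries, 7 and 7 changed in the p50 knockout, 10 and 6 in the p52 knockout, 1 and 3 in the RelA knockout, and 11 and 8 in the RelB-labelled libraries. Of 24 EBV super-enhancer and growth genes, the numbers that rose and fell were 1 and 2, 5 and 6, 6 and 8, 2 and 1, and 11 and 6 in the same order. Markers of other cell types served as a check: of 5 tested T and NK cell markers the numbers were 0 and 1, 0 and 1, 0 and 1, 0 and 0, and 2 and 1. The highest of these was NKG7, at 411 ± 71.3 in the control, which fell to 299 ± 12.6 in the cRel-labelled and rose to 675 ± 45.5 in the RelB-labelled libraries. The highest monocyte marker was CSF1R, at 389 ± 17.6 in the control, which rose to 653 ± 43.2 in the p50 knockout, 639.6 ± 51.8 in the p52 knockout and 747 ± 15.5 in the RelB-labelled libraries, the groups in which 26 or 27 of 27 proliferation genes passed as lower. Summed values of the 10 measured monocyte markers were 551 ± 6.41 in the control, 664 ± 50.8 in the cRel-labelled libraries, 905 ± 41.6 in the p50 knockout, 952 ± 61.6 in the p52 knockout, 539 ± 26.8 in the RelA knockout and 1021 ± 34.8 in the RelB-labelled libraries. CSF1R made up most of each sum, so the sums are not separate from its values. Only 3 of the 10 markers were tested, and the median marker stood at 3.52 in the control. The highest epithelial or fibroblast marker was COL1A1, at 1250.4 ± 109.8 in the control, which fell to 803 ± 157 in the p50 knockout and did not pass in the other groups (means of 1067 to 1392). Too few monocyte, epithelial and fibroblast markers were tested for camera.

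**Figure D3:**
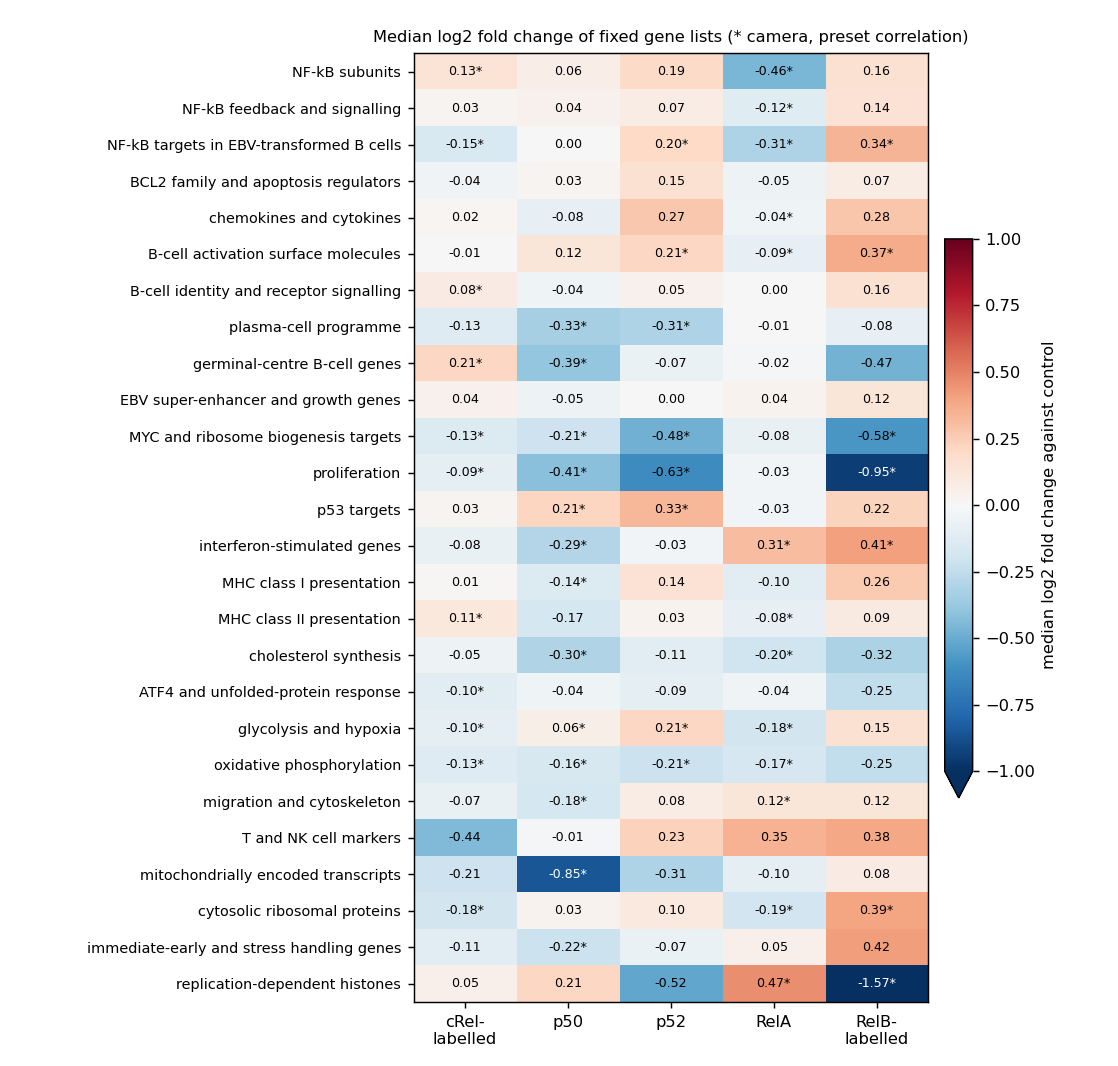
Median log2 fold change of each gene list (lines) in each knockout against control (columns), with colour for the median and an asterisk where limma's camera with a preset correlation gave an adjusted p under 0.05. Proliferation genes had medians of -0.41, -0.63 and -0.95 in the p50, p52 and RelB columns, and the histone median of -1.57 in the RelB column lies below the end of the colour scale at -1.

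The 5 knockouts were then compared with one another. The F-test among them called 9756 genes (limma; 9764 with edgeR and 9702 with DESeq2). CCL22 had the smallest p (adjusted p = 1.1e-18). It stood at 494 ± 64.0 in the cRel-labelled libraries, 1355 ± 55.2 in the p50 knockout, 2120 ± 12.1 in the p52 knockout, 1839 ± 56.7 in the RelA knockout and 7254 ± 136 in the RelB-labelled libraries, against 2559 ± 245 in the control. FSTL3 was below the control value of 763 ± 62.1 in the RelA, p50 and cRel groups, at 141 ± 11.2, 184 ± 38.6 and 299 ± 32.6, and above it in the p52 and RelB groups, at 1389 ± 84.1 and 1255 ± 112. EBI3 ranged from 2948 ± 218 in the RelA knockout to 11705 ± 481 in the RelB-labelled libraries. TNFRSF14, the herpesvirus entry mediator, ranged from 1031 ± 9.94 to 4713 ± 133 between the same groups. SMIM14 ranged from 383 ± 14.3 in the RelB-labelled to 2313 ± 160 in the cRel-labelled libraries. VIM stood at 1581 ± 98.8 in the p50 knockout, at a mean of 1348 in the RelB-labelled libraries and at 4184 ± 212 to 4494 ± 195 in the other knockouts.

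**Figure D4:**
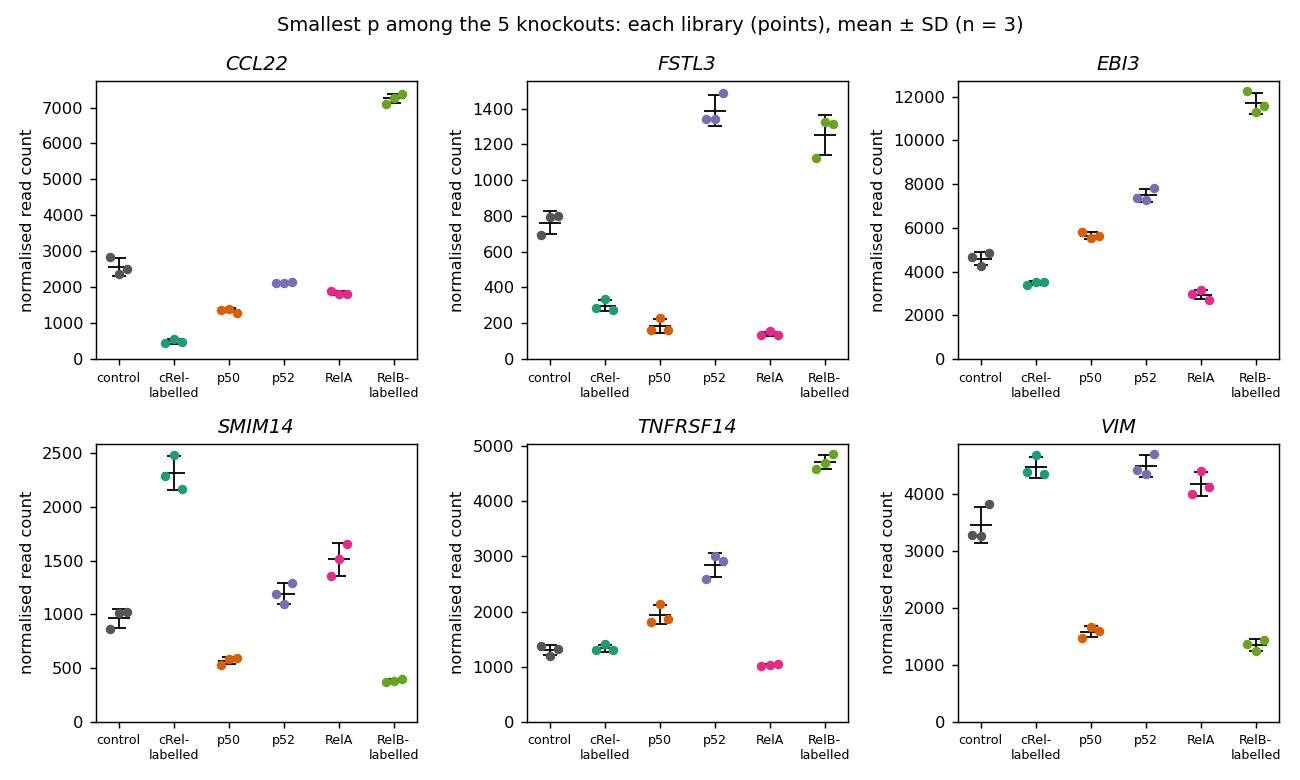
Normalised read counts of the 6 genes with the smallest p in the F-test among the knockouts, 1 panel per gene; each point is a library, and the long line and error bar are the mean and SD of 3. CCL22 lay at 494 in the cRel-labelled and 7254 in the RelB-labelled libraries.

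Direct tests of pairs of knockouts called from 1356 genes, between the cRel-labelled libraries and the RelA knockout, to 8318, between the RelA knockout and the RelB-labelled libraries. The p50 and p52 knockouts differed in 2749 genes. The cRel-labelled libraries differed from the p50, p52 and RelB groups in 3855, 5681 and 8144 genes, the p50 knockout from the RelA and RelB groups in 4853 and 6575, and the p52 knockout from the same groups in 6494 and 5622. Proliferation genes were lower in the RelB-labelled libraries than in the p52 knockout (21 of 27 past the test; median difference 0.34, camera adjusted p = 1.6e-06, and adjusted p = 0.32 with an estimated correlation). They were also lower in the p52 than in the p50 knockout (14 of 27; 0.18, adjusted p = 6.8e-06, and adjusted p = 0.28 with an estimated correlation). NF-kB targets were higher in the p52 knockout and in the RelB-labelled libraries than in the RelA knockout (adjusted p = 7.0e-08 and 4.8e-06, and adjusted p = 0.072 and 0.086 with an estimated correlation). Of the 39 targets 27 were higher and 5 lower in the p52 knockout, and 28 were higher and 9 lower in the RelB-labelled libraries. Interferon-stimulated genes were higher in the RelA knockout than in the cRel, p50 and p52 groups (adjusted p = 6.3e-12, 9.6e-09 and 1.0e-04, and adjusted p = 0.061, 0.13 and 0.22 with an estimated correlation). The difference from the RelB-labelled libraries did not pass (adjusted p = 0.83). Mitochondrially encoded transcripts were lower in the p50 knockout than in the RelA knockout (12 of 13 past the test; -0.72, adjusted p = 8.6e-04, and adjusted p = 0.50 with an estimated correlation). Against the p52 knockout 1 of 13 passed singly (-0.44, adjusted p = 0.0019, and adjusted p = 0.47 with an estimated correlation). Histone genes were lower in the RelB-labelled libraries than in the RelA knockout by a median of 2.07 (11 of 12 past the test, adjusted p = 8.8e-06, and adjusted p = 0.19 with an estimated correlation). Of 260 list tests between pairs, 124 were called with the preset correlation and 2 with an estimated one. Both were between the cRel-labelled libraries and the RelA knockout. NF-kB feedback genes were higher in the former (12 of 26 higher, 1 lower; median difference 0.23, adjusted p = 3.0e-07, and adjusted p = 0.036 with an estimated correlation). So were the subunit genes (4 of 5 higher, 0 lower; 0.59, adjusted p = 2.8e-08, and adjusted p = 0.019 with an estimated correlation), a list that holds the targeted genes RELA and REL.

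Many calls were shared between the p50, p52 and RelB groups. The p50 and p52 knockouts shared 1621 genes that rose and 1908 that fell, against 516 and 641 for independent lists. The p50 knockout and the RelB-labelled libraries shared 1706 and 1996, against 698 and 843, and the p52 knockout and the RelB-labelled libraries 2319 and 2665, against 1002 and 1133. Across genes, which are not independent replicates, the covariance of the log2 fold changes in these pairs was 0.122, 0.165 and 0.234. Groups simulated without change against a shared simulated control gave a covariance of 0.01204 (-0.002075 to 0.03153 over 100 draws). That control was drawn from the deviations of all libraries, so this range need not hold for the 3 real controls, of which control 3 stood apart. The RelA knockout and the cRel-labelled libraries shared 86 and 38 genes, against 15 and 6.27, with a covariance of 0.0170, inside the simulated range. The RelA knockout shared 131 and 62 with the p50 knockout (61.5 and 64.0 for independent lists), 178 and 47 with the p52 knockout (88.3 and 86.0) and 205 and 94 with the RelB-labelled libraries (119 and 113). The covariances were 0.0105, 0.00995 and 0.0268, inside the simulated range and, for p50 and p52, below the simulated mean. The RelA knockout had opposite calls in 186 and 222 genes with the p50 and p52 knockouts, against 193 and 225 in the same direction. The cRel-labelled libraries shared 245 and 92 with the p50 knockout (87.9 and 46.7), 384 and 117 with the p52 knockout (126 and 62.8) and 319 and 97 with the RelB-labelled libraries (171 and 82.5). The covariance of 0.0267 with the p50 knockout lay inside the simulated range, and those of 0.0494 and 0.0367 with the p52 and RelB groups lay above it. With 3 controls common to all comparisons and too few to split, part of each excess can come from the controls themselves.

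Altogether 9861 genes were called in at least 1 knockout and 89 in all 5, of which 35 were higher in all and 3 were lower in all. The 3 were TNF, the survival gene BCL2L1, with log2 fold changes of -0.67, -0.63, -0.47, -0.29 and -0.68 in the cRel, p50, p52, RelA and RelB groups, and FKBP11, a chaperone of secretory cells, at -0.30, -0.29, -0.48, -0.40 and -0.36. TNF stood at -0.37, -0.44, -0.95, -0.38 and -2.33. These genes fell outside the rule for named genes, apart from TNF in the RelB-labelled libraries, and are given because their number was small, after their values were seen.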

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

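The tests of exchanged labels, the length and GC correction, the thinning of reads to one depth and the tests with an estimated correlation between pairs of knockouts were chosen after the data were seen; the splits and the tests that leave out 1 library were not. Splits of the libraries are given with the number of genes or gene lists called.

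RELB mRNA was higher in the RelB-labelled libraries than in the control (log2 fold change 0.31), and REL mRNA was not lower in the cRel-labelled libraries (-0.02, SE 0.19). An exchange of the RelA and RelB labels is not excluded, but the RELA values favour the labels as given. RELA stood at 0.156 in the RelB-labelled libraries and fell by 0.69 in those labelled RelA. RELB, however, fell by 0.82 in the latter, its lowest level of all groups. An exchange of the cRel and RelB labels is not excluded either. REL stood at -0.492 in the RelB-labelled libraries, while RELB stood at 0.38 in the cRel-labelled libraries. The REL call depended on single libraries, with controls 1, 2 and 3 at 1554, 1717 and 856. What keeps both open is that a CRISPR edit need not lower mRNA and that protein levels are not analysed here. The labels' protocols state a check by immunoblot, whose results were not examined. An unchanged or raised mRNA of an edited gene is the biological reading the design gives, and it was not tested.

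Proliferation genes were lower in the p50 and p52 knockouts and the RelB-labelled libraries, with medians of -0.41, -0.63 and -0.95 and 26, 27 and 27 of 27 past the test. Unusual control libraries as the whole cause are argued against, since the medians against the RelA knockout libraries were -0.364, -0.56 and -0.93. A trend with transcript length or GC content is argued against too, since after correction the medians were -0.409, -0.58 and -0.91. An effect of the knockouts on growth, culture density, time since selection and the number of edited clones per culture stay open, and none of them was tested.

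Ribosomal protein genes were lower in the cRel-labelled libraries and the RelA knockout, with medians of -0.18 and -0.19. With reads thinned to one depth the median in the RelA knockout was -0.190. Random thinning followed by rescaling cannot shift the ratios of genes with this many reads. It therefore does not decide whether the greater depth of control 3 played a part. The excess of short transcripts in control 3 may account for part of the difference: without that library the medians were -0.0950 and -0.0950, with adjusted p = 0.0085 and 0.0043 by limma's camera at the preset correlation. With all libraries the adjusted p was 0.47 and 0.50 with an estimated correlation, and 0 of 33 genes passed singly by limma, with 14 and 13 lower at an unadjusted p under 0.05. An effect of the knockouts stays open for the rest. Without any control the list was also lower than in the p50 knockout (differences of -0.23 for cRel minus p50 and 0.22 for p50 minus RelA, with camera adjusted p = 0.50 and 0.57 with an estimated correlation). Such a difference cannot show which of the 2 groups moved.

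Some genes changed in opposite directions in 2 knockouts; the direct difference was also called for each of them, which the choice of such genes makes nearly certain and which adds no evidence. The examples were chosen after their values were seen. Between the cRel-labelled libraries and the p50 knockout there were 108 such genes, such as SMIM14 (1.26 and -0.75). Between the cRel-labelled libraries and the p52 knockout there were 65, such as FSTL3 (-1.35 and 0.86). The cRel-labelled libraries and the RelA knockout had 61, such as TNFRSF9 (0.74 and -1.84). The cRel-labelled and RelB-labelled libraries had 175, such as CCL22 (-2.37 and 1.51) and BCL6 (0.90 and -2.62). For the p50 and p52 knockouts the number was 103, among them IGFBP3 (1.56 and -0.73). For the p50 and RelA knockouts it was 186, among them DBNDD1 (2.33 and -0.79). The p50 knockout and the RelB-labelled libraries had 187, such as HIST1H1C (0.72 and -2.39). The p52 and RelA knockouts had 222, such as FAM129C (-1.35 and 1.37). The p52 knockout and the RelB-labelled libraries had 224, such as EGR1 (-0.49 and 1.96). The RelA knockout and the RelB-labelled libraries had 218, such as RGS1 (-0.65 and 2.89). For independent lists the expected numbers were 142, 194, 20.5, 258, 1151, 126, 1536, 175, 2131 and 233 in this order, so that only the cRel and RelA, p50 and RelA, and p52 and RelA counts were above expectation.

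Of the 100 splits of the knockout libraries compared for the F-test, only 1, the real one, called 9756 genes, against at most 1098 in the others. This argues against a random assignment of libraries to groups as the source of that count. Splits that mix groups also add the group differences to the spread, which lowers their counts. Differences that arose by chance between edited cultures cannot be told apart in this way. For each knockout against control and each pair of knockouts, the 6 libraries allow 10 splits, too few for a share under 0.05. The real split, 1 of 10, called 754, 4539, 6295, 687 and 8391 genes for the cRel, p50, p52, RelA and RelB groups, and the highest of the other splits called 0 in each case. For the 10 pairs the real split, again 1 of 10, called 1356 to 8318 genes and the highest other 0. Gene lists called by camera were 11 for the cRel group against 9 in the highest other split, 13 for p50 against 8 and 13 for RelA against 9, with 1 of 10 splits as large. They were 8 for p52 and 7 for RelB against 11 and 11, with 5 of 10 splits as large. Camera with a preset correlation thus called lists in splits without a called gene.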

How the results depend on the processing

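TMM rescaling, the length and GC correction, control 3 and p52 3 left out together, and thinning to one depth were chosen after seeing the data. Under none of these or the earlier settings did a called direction reverse for a named gene or a list, and the percentage of called genes that rose moved by less than 10 points. Genes changed in the cRel-labelled libraries and in the RelA knockout numbered 1137 and 1117 with library weights, against 754 and 687; the cause was not tested. With a library left out in turn they ranged from 448 to 821 and from 413 to 848, the p50 count from 3377 to 4370, the p52 count from 5443 to 6195, the RelB count from 7873 to 8021 and the F-test count from 9334 to 9847. With an estimated correlation camera called 0, 0, 0, 3 and 0 lists for the cRel, p50, p52, RelA and RelB groups against 11, 13, 8, 13 and 7. The 3 include the subunit list, which holds the targeted RELA. The estimated correlations were all above the preset 0.01. They ran from 0.024 for B-cell identity genes to 0.91 for mitochondrially encoded transcripts, with 0.37 for proliferation genes. Most list calls thus rest on the low preset value. For the RelB group camera with the preset correlation called 12 lists without a filter, 11 at a mean of at least 100 and 14 after quantile normalization. The cause was not tested. With a library left out the list counts were 8 to 13, 11 to 13, 7 to 10, 10 to 15 and 7 to 9 in the same order. The log2 fold changes of the targeted genes with a library left out were -0.33 to 0.17 for REL, -0.61 to -0.56 for NFKB1, -0.46 to -0.42 for NFKB2, -0.71 to -0.67 for RELA and 0.27 to 0.34 for RELB; only REL in the cRel-labelled libraries changed sign, and it was not called. Of 143 named gene results that were called, 8 were lost under at least 1 setting, 7 of them when 1 library was left out, and 0 reversed. Among values for single lists, 65 became called, 64 lost the call and 2466 did not change side; for single genes these numbers were 9, 35 and 3283. After the length and GC correction the counts were 1022, 5133, 6931, 903 and 8798, and with the replicate block 940, 4870, 6557, 834 and 8557. The block was not used as the main setting, though 16 of 18 libraries correlated best with a library of their own number. Without control 3 and p52 3 the counts were 580, 4244, 5730, 600 and 8269, and with reads thinned to one depth 636, 4126, 5956, 553 and 8060. The median-ratio rescaling moved nothing and tests nothing. The smallest simulated changes in the cRel comparison were found for 20 of 50 genes at these depths, so a change of that size that was not called is not shown to be absent.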

Other observations

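The genes in this part were chosen after their values were seen. Regulators of cell survival moved in different directions. BCL2L1, which encodes the survival factor BCL-XL, was lower in all 5 groups, while BCL2, another survival factor, rose in the p50 and p52 knockouts and the RelB-labelled libraries (log2 fold changes 0.74, 0.81 and 1.51; adjusted p = 2.5e-06, 1.6e-07 and 3.2e-12 by limma) and stood at 0.25 and -0.05 in the cRel and RelA groups. In the RelB-labelled libraries BCL2L11, the pro-apoptotic BIM, fell by 1.07. MYC rose by 1.35 in the RelB-labelled libraries (adjusted p = 1.3e-11), where 22 of 24 MYC and ribosome biogenesis targets fell; it was lower in the cRel and p52 groups (-0.40 and -0.42). The p53 targets in the RelB-labelled libraries were not called as a list (13 of 26 rose, 6 fell), with CDKN1A, the cell-cycle inhibitor p21, at 0.59 and MDM2, which degrades p53, at -0.47.

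PRDM1 was lower in the cRel, p50, p52 and RelB groups (-0.37, -1.04, -1.26 and -1.56), and higher in the RelA knockout (0.38). EBF1, an early B-cell factor, was higher in all 5 groups (0.41, 0.40, 0.43, 0.23 and 1.09). The checkpoint ligand CD274 stood at 0.51, 0.81, 0.88, 0.14 and 1.89, and PDCD1LG2 at 0.53, 0.12, 1.02, 0.54 and 1.74. HSPA5, the main chaperone of the endoplasmic reticulum, fell in the p50, p52 and RelB groups (-0.68, -0.92 and -0.99). The Notch ligand DLL4 was higher in all 5 groups (1.55, 1.80, 2.57, 0.93 and 2.74).

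In the RelB-labelled libraries, of 142 long noncoding genes with a mean of at least 100, 71 rose and 28 fell (median 0.24). The numbers were 2961 and 3924 of 9654 protein-coding genes (median -0.08). Of 51 genes in neither class 27 rose and 8 fell (median 0.31), so the shift was not particular to long noncoding genes. The long noncoding class includes antisense genes, whose reads were not separated from those of their partners. Of the 142 long noncoding genes 4 rose and 3 fell in the cRel group, 28 and 9 in the p50 group, 36 and 16 in the p52 group, and 1 and 9 in the RelA group, where 279 protein-coding genes rose and 278 fell. Across 9840 genes, which are not independent replicates, the rank correlation of the log2 fold change with transcript length was 0.44, 0.24, 0.15, 0.43 and 0.17 in the cRel, p50, p52, RelA and RelB groups, and 0.17, 0.07, 0.03, 0.13 and 0.09 without control 3.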
